A study of Mus musculus with 34 samples.

How the data were processed

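Mouse bone-marrow-derived macrophages, grown for 7 days per the labels, were measured on Affymetrix MG-U74Av2 arrays: 12488 probe sets on 34 arrays. Per the labels, the cells were resting (4 arrays) or received LPS at 100 ng/ml for 45 or 180 min, alone, with IL-10 at 10 ng/ml, or with IL-6 at 2 ng/ml. The stimulated cells were wild type, IL-10-/- or IL-6-/-, and the IL-6 arm exists at 45 min alone. Each stimulated group held 2 arrays, which the titles call biological replicates, apart from IL-6-/- with LPS alone, which held 1 array at each time. The lone array was assumed to vary as the arrays of the other groups did. The labels give no genotype for the resting arrays. They also name the CSF-1 source differently for resting cells (L-cell conditioned medium) and stimulated cells (mCSF). Of the 34 arrays, 32 entered a group; 1 title without a genotype and 1 array whose title and treatment protocol disagree on the time entered no comparison.

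The values are the intensity of each probe set as deposited by the authors, on a linear scale from 0.2 to 86349.8. Per the submitters' processing notes they came from MAS5, whose version the notes do not give. The 2% trimmed mean of every array lay between 500.29 and 500.4, so each array had been scaled to 500 by the authors. These values are called signal below. No count model was used, since the values are not counts, and the arrays were not scaled again.

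Gene names came from a platform table that lists 11251 probe sets, of which 10855 carry 1 symbol and 396 several; 1237 probe sets are not listed. Entrez identifiers matched 10839 symbols to the RefSeq gene table of GRCm38.p6, which was used for names and gene order alone, and 0 symbols changed. The 66 control probe sets were left out of all tests, leaving 12422. Probe sets with a signal of at least 200 in at least 2 of the grouped arrays were tested: 8224, standing for 6070 genes. A gene is given by its probe set with the highest mean. The other probe sets of every named gene were looked up, and none passed the threshold in the opposite direction.

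Signals were transformed to log2 of the signal plus 50. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over the 16 groups (lmFit, then eBayes with an intensity trend), with 16 residual degrees of freedom and 7.575 prior degrees of freedom. There were 20 comparisons: LPS against resting at each time; added IL-10 at each time and added IL-6 at 45 min, in each genotype and as the mean of the 3 genotypes; IL-10 against IL-6; each knockout against wild type under LPS; and the difference of the IL-10 response at 180 min between IL-10-/- and wild type. P-values of genes are 2-sided from limma, adjusted by Benjamini-Hochberg over the probe sets of a comparison, and a call means an adjusted p under 0.05. Log2 changes carry their standard error. The p-values measure the spread between these arrays, and the labels do not say how many mice stand behind them.

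The 19 gene lists were fixed before the data were seen: inflammatory cytokines; chemokines; inflammatory enzymes, receptors and costimulation; STAT3-linked IL-10 targets; cytokine receptors, JAK, STAT and SOCS; interferon response; NF-kappaB components and feedback; immediate early genes; antigen presentation (MHC class II); macrophage identity; sterol synthesis and efflux; glycolysis and hypoxia; cell cycle; heat shock and stress; neutrophil and granulocyte; lymphocyte; stromal; erythroid and mast cell; dendritic cell. They were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Camera ranks a list against all other genes, so a list can pass while few of its members do. Genes to name were picked by a fixed rule: the 6 largest rises and the 6 largest falls that passed, up to 4 members of each responding list, and Il10, Il6, Socs3, Tnf, Il12b and Bcl3 throughout.

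The alternatives tried were a pseudocount of 10 or 200, no filter, a filter at 500, quantile normalization, eBayes without a trend, a replicate block, camera with an estimated correlation, the mean of all probe sets of a gene, the mean of wild type and IL-10-/- alone, and 104 fits that each left out 1 array of a comparison. Leaving out resting replicate 4 was added after the data were seen, for the 18 comparisons that do not use resting cells. Replicate numbers run through the titles, so it was checked whether arrays with the same number vary together. Over the 23 pairs of groups within a genotype the correlation of the replicate differences ran from 0.0204 to 0.441 (median 0.12), and 13 exceeded 0.1. A comparison of means was to be blocked when every genotype that could be checked exceeded 0.1, a rule fixed before the correlations were seen. This held for the IL-6 arm (0.182 in wild type, 0.207 in IL-10-/-), where the block gave 51 probe sets in place of 45 and changed no named gene or list, so the unblocked values are given. It did not hold for IL-10 at 45 min (0.0554 and 0.144), IL-10 at 180 min (0.299 and 0.0976) or IL-10 against IL-6 (0.0204, 0.113 and 0.441).

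Median signals ran from 158 to 237.3, and 45.1% to 55.02% of probe sets reached 200. Detection calls were not used, so low signals cannot be told from background, and sizes of changes from or to them depend on the pseudocount. Replicates correlated at 0.932 to 0.960 in stimulated groups and at 0.863 to 0.930 among the resting arrays. The fit was tested on simulated data with 200 of 8224 probe sets changed. At a 2-fold change it recovered 41.8% for LPS at 180 min, 31.3% for IL-10 in wild type, 16.4% for IL-10 in IL-6-/-, 70.1% for the mean of the 3 genotypes and 7.46% for the difference between genotypes, with 4 to 6 false calls. At 4-fold these shares were 89.4%, 86.4%, 81.8%, 100% and 51.5%. On simulated data camera called a list of 37 shifted by 0.5 log2 (adjusted p = 2e-09) and 0 of 18 others, leaving correlated lists untested. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.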

Results

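The targeted genes were read first in every group. The Il10 probe set gave a mean signal of 346.4 in resting cells, 2523 and 2983 in wild type after 45 and 180 min of LPS, and 6185 and 1522 in IL-10-/- at the same times. With added IL-10 it reached 9496 at 45 min and 4666 at 180 min in IL-10-/-, and with added IL-6 8179 at 45 min. The Il6 probe set gave 64.8 in resting cells, 215.8 and 3606 in wild type with LPS, 180.4 and 24170 in IL-10-/-, and 617.8 and 1014 in IL-6-/-. In IL-6-/- it gave 7674 with IL-10 and 3333 with IL-6 at 45 min, and 433.9 with IL-10 at 180 min. Both probe sets therefore gave signal in their own knockouts. Where they lie relative to the deleted parts is unknown, so these values check neither genotype, and Il10 or Il6 changes within the own knockout speak of transcript from the locus rather than of cytokine.

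**Figure D1:**
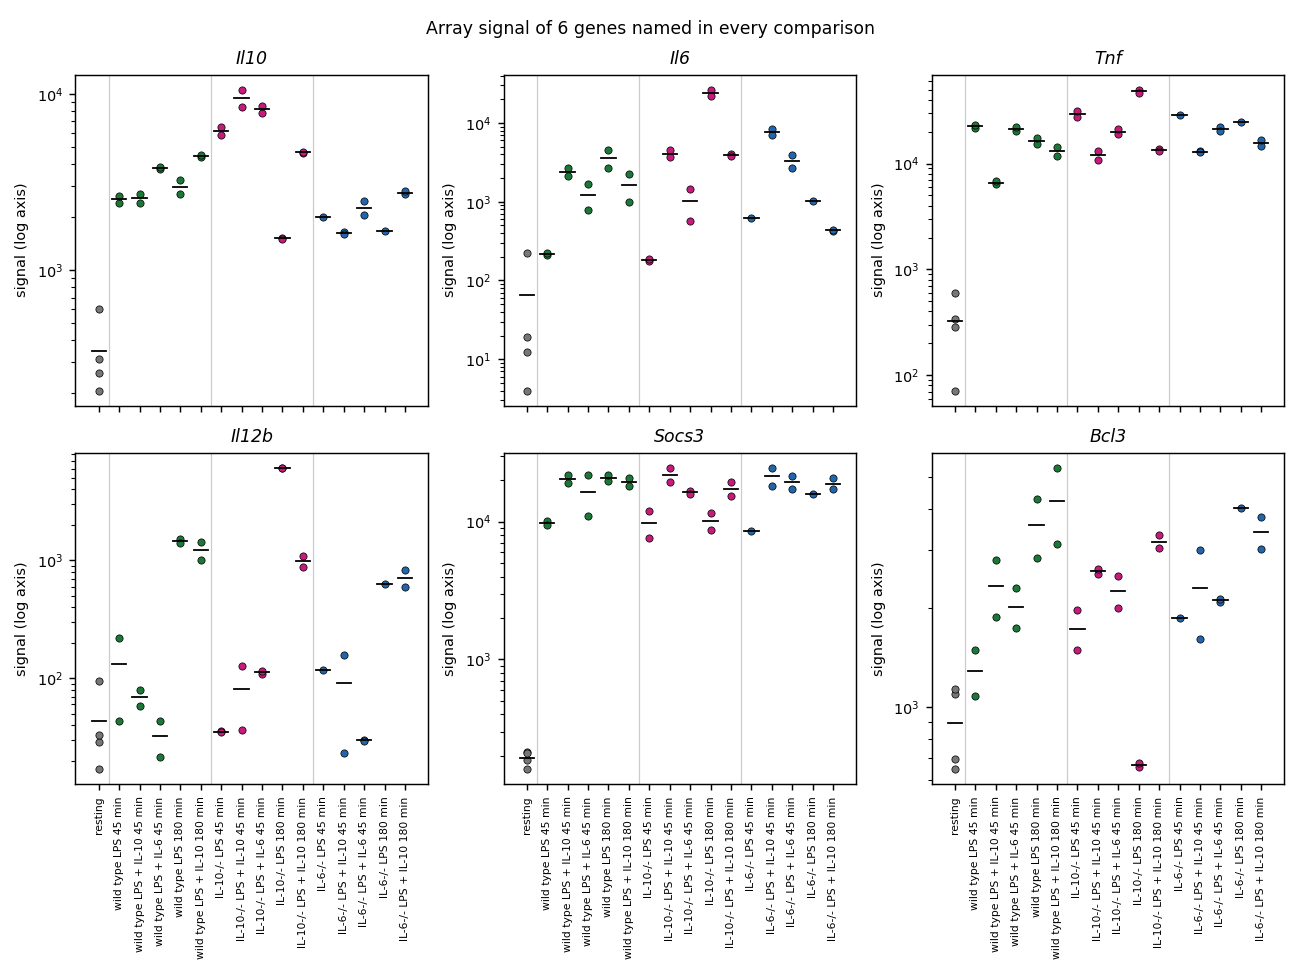
Signal of Il10, Il6, Tnf, Il12b, Socs3 and Bcl3 in each array, by group, on a logarithmic axis.

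After 45 min of LPS the chemokine genes Cxcl2 and Cxcl1, the cytokine genes Il1b and Tnf, the TNF-family ligand gene Tnfsf9 and Phlda1 were higher. Prostaglandin synthase 2 (Ptgs2), the feedback genes Socs3, Dusp1, Nfkbiz and Nfkbia, and the immediate early genes Fos and Ier2 rose with them. The monocyte chemokine receptor gene Ccr2, the protease gene Adam28, Ly86 (encoding a partner of the LPS-receptor relative RP105) and the proteasome genes Psmb9 and Psme1 were lower. Collagen and other stromal genes were also higher than in resting cells, a difference already as large at 45 min as at 180 min.

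Of 8224 probe sets, 1377 changed after 45 min of LPS in wild type (740 higher, 637 lower; 708 and 736 after quantile normalization; n = 2 against 4 resting arrays). The count dropped to 718 without LPS replicate 1 and to 695 without replicate 2. Cxcl2 rose 134-fold (log2 change 7.06 ± 0.28, adjusted p = 1.6e-15), Cxcl1 125-fold, Il1b 76.3-fold, Tnf 71.1-fold (6.15 ± 0.34), Tnfsf9 65.9-fold and Phlda1 51.6-fold. Folds over low resting signals, such as 115.5 for Cxcl1, depend on the pseudocount here and at 180 min. Socs3 rose 40.5-fold and Il10 6.92-fold (adjusted p = 1.37e-09). Il6 rose by 1.57 ± 0.46 (adjusted p = 0.0209), but not without LPS replicate 1 (0.106), LPS replicate 2 (0.124) or resting replicate 3 (0.056). Il12b, which encodes the p40 subunit of IL-12 (0.83, adjusted p = 0.157), and Bcl3 (0.52, 0.192) did not pass. Ccr2 fell by 3.01 ± 0.38, Adam28 by 2.40, Ly86 by 2.33, and Rcan3, a calcineurin regulator, by 2.23. Ints9 fell by 2.22.

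Of the 36 immediate early genes tested, 24 rose, none fell and 12 did not pass (26 rose adjusted over the list alone, list adjusted p = 3.34e-28), among them Ier2, Fos and Sgk1 (15.1-, 20.8- and 8.63-fold). Of 11 inflammatory cytokines 6 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone, adjusted p = 5.58e-09), with Il1a up 32.3-fold. Among 16 chemokines 9 rose and 7 did not pass (9 up and 2 down adjusted over the list alone, adjusted p = 2.52e-08), with Ccl2 up 44.3-fold and Ccl7 29.6-fold. Inflammatory enzymes, receptors and costimulation counted 12 risers and 12 that did not pass of 24 (14 adjusted over the list alone, adjusted p = 6.86e-11): Ptgs2 38.2-fold, Cd83 19.1-fold, Icam1 7.68-fold. STAT3-linked IL-10 targets held 9 risers, 2 fallers and 8 others of 19 (10 and 2 adjusted over the list alone, adjusted p = 9.68e-08), with Dusp1 up 29.4-fold and Il1rn, the IL-1 receptor antagonist gene, 3.48-fold. NF-kappaB components and feedback had 10 up, 1 down and 16 not passing of 27 (10 and 1 adjusted over the list alone, adjusted p = 1.69e-05), led by Nfkbiz (30.9-fold), Tnfaip3 (35.9-fold) and Nfkbia (10.3-fold). Heat shock and stress genes had 8 up, 1 down and 18 not passing of 27 (9 and 1 adjusted over the list alone, adjusted p = 0.000816), such as Dnaja1 (2.70-fold), Hsp90aa1 (2.22-fold) and Txnrd1 (2.22-fold).

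The interferon response lay below resting at 45 min: 22 of 37 genes were lower, 3 higher and 12 did not pass (25 and 3 adjusted over the list alone). Its median was -1.08 and its list adjusted p 2.52e-08 (adjusted p = 0.204 with an estimated correlation). How much of this came from the resting cultures rather than from LPS was not tested. Psmb9 fell by 1.73 and Psme1 by 1.38, while Irf1 rose 5.16-fold and Ifi202b 9.39-fold. Of 34 cell cycle genes 6 fell and 28 did not pass (8 fell adjusted over the list alone, adjusted p = 0.00176, adjusted p = 0.302 with an estimated correlation). Its member Mcm5 fell by 1.70, though not without LPS replicate 1 (adjusted p = 0.117). Macrophage identity had 9 fallers, 1 riser and 18 others of 28 (9 and 1 adjusted over the list alone, adjusted p = 0.0255), including C1qb, which fell by 0.86; Cd14 rose 1.72-fold. That list lost its call with an estimated correlation (adjusted p = 0.175), after quantile normalization (0.131), without LPS replicate 2 (0.0625) and without resting replicate 1 (0.14). Of 10 neutrophil and granulocyte genes 3 fell and 7 did not pass (4 fell adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.157 with an estimated correlation; 0.0937 without LPS replicate 2, 0.0686 without resting replicate 4). All 12 stromal genes tested, of 14 on the array, rose (12 adjusted over the list alone, adjusted p = 5.37e-14), with Lox up 11.9-fold, Col1a2 11.2-fold and Fn1 6.89-fold.

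The remaining lists did not pass at 45 min. Cytokine receptors, JAK, STAT and SOCS counted 4 up, 4 down and 21 neither of 29 (4 and 4 adjusted over the list alone, adjusted p = 0.691), with Stat5b down by log2 -1.71 and the phosphatase gene Ptpn6 by -0.95. Antigen presentation had 2 fallers and 10 others of 12 (2 adjusted over the list alone, adjusted p = 0.305). In sterol synthesis and efflux 4 rose and 16 did not pass of 20 (4 adjusted over the list alone, adjusted p = 0.403). Glycolysis and hypoxia genes split, with 3 up, 6 down and 11 neither of 20 (5 and 8 adjusted over the list alone, adjusted p = 0.439), where the median was -0.03, the mean 0.02 and the direction of the test down. Tpi1 and Pkm each fell by 0.87 and Ldha by 0.73. Of 9 lymphocyte genes 1 rose and 8 did not pass (1 adjusted over the list alone, adjusted p = 0.671). Erythroid and mast cell genes had 1 riser and 5 others of 6 (1 adjusted over the list alone, adjusted p = 0.836; median -0.09, mean 0.02, test up). Dendritic cell genes likewise had 1 and 5 of 6 (1 adjusted over the list alone, adjusted p = 0.691).

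After 180 min of LPS the same inflammatory genes stayed high and many more followed. Ptgs2, Il1b, Il1a, Cxcl1, the acute-phase gene Saa3 and the itaconate-producing enzyme gene Acod1 were among the largest rises, and Il6, Il12b and Bcl3 had now risen too. The stress sensor gene Sesn1, the chemokine receptor genes Cxcr4 and Ccr2, the ceramide kinase gene Cerk, the transcription factor gene Lyl1 and the G-protein regulator gene Rgs2 fell most.

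There were 2778 changed probe sets (1181 higher, 1597 lower; n = 2 against 4). Il1b rose 154-fold and Saa3 142-fold. Ptgs2 (13.42 to 9837, adjusted p = 2.19e-19), Cxcl1 (115.5 to 21560), Il1a (46.98 to 13160) and Ifi202b (11.12 to 7504) rose from signals too low for an exact fold. Tnf stood 51.2-fold above resting (5.68 ± 0.34), Il6 39.5-fold (5.30 ± 0.46, adjusted p = 2.21e-09), Il12b 17-fold (1.46e-08), Il10 8.13-fold, Socs3 85.7-fold and Bcl3 3.86-fold (3.41e-06). Sesn1 fell by 5.09 ± 0.34, Cxcr4 by 4.87, Ccr2 by 4.40, Cerk by 4.29, Lyl1 by 4.17 and Rgs2 by 4.12.

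By list, 9 of 11 inflammatory cytokines rose and 2 did not pass (9 adjusted over the list alone, list adjusted p = 1.94e-12). So did 14 of 16 chemokines, with 2 not passing (14 adjusted over the list alone, adjusted p = 6.37e-15), among them Ccl3 (28.7-fold) and Ccl2 (40.5-fold). Inflammatory enzymes, receptors and costimulation showed 22 of 24 up and 2 not passing (23 adjusted over the list alone, adjusted p = 4.27e-26), with Acod1 up 87.3-fold, Il1rn 52.1-fold and Icam1 29.2-fold. STAT3-linked IL-10 targets had 15 up, 1 down and 3 neither of 19 (17 and 1 adjusted over the list alone, adjusted p = 4.93e-14), including Il4ra (7.43-fold) and Dusp1 (10.9-fold). Of 29 cytokine receptors, JAK, STAT and SOCS genes 14 rose, 2 fell and 13 did not pass (14 and 3 adjusted over the list alone, adjusted p = 1.33e-05), with Jak2 up 16-fold and Stat5a 4.40-fold. NF-kappaB components and feedback counted 20 up, 1 down and 6 neither of 27 (22 and 1 adjusted over the list alone, adjusted p = 8.39e-17): Nfkbiz 26.1-fold, Tnfaip2 14.3-fold, Map3k8 12.9-fold and Tnip1 6.46-fold. Immediate early genes were mixed, 18 up, 7 down and 11 neither of 36 (18 and 7 adjusted over the list alone, adjusted p = 0.000124), with Errfi1 (20.9-fold), Gadd45b (16.9-fold) and Dusp2 (11.4-fold) up.

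The interferon response stood above resting at 180 min, with 20 of 37 genes higher, 5 lower and 12 neither (21 and 5 adjusted over the list alone, adjusted p = 8.15e-05, adjusted p = 0.347 with an estimated correlation). Gbp3 rose 12.2-fold, Peli1 8.81-fold and Irf1 3-fold. Glycolysis and hypoxia had 8 up, 2 down and 10 neither of 20 (8 and 2 adjusted over the list alone, adjusted p = 0.000724): Adm 15-fold, Slc2a1, the glucose transporter gene, 10.8-fold, Hk2 7.76-fold and Hif1a 4.21-fold. Heat shock and stress counted 12 up, 2 down and 13 neither of 27 (13 and 2 adjusted over the list alone, adjusted p = 3.65e-05), led by Mt2 (17.4-fold) and Sod2 (15.6-fold). Sterol synthesis and efflux had 7 up, 2 down and 11 neither of 20 (7 and 2 adjusted over the list alone, adjusted p = 0.0167, adjusted p = 0.0599 with an estimated correlation), with Ch25h up 16.5-fold and Hmgcs1 4.29-fold. Of 34 cell cycle genes 17 fell, 2 rose and 15 did not pass (19 and 3 adjusted over the list alone, adjusted p = 0.0044, adjusted p = 0.343 with an estimated correlation). Mcm7 fell by 2.12 and Cdk1 by 2.08, while Ccnd2 rose 7.60-fold. All 12 tested stromal genes were again higher (12 adjusted over the list alone, adjusted p = 2.21e-09), for example Lox (11.7-fold) and Col5a2 (4.10-fold).

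At 180 min the other lists did not pass. Macrophage identity had 14 down, 3 up and 11 neither of 28 (15 and 3 adjusted over the list alone, adjusted p = 0.0767): C1qb fell by 1.13, whereas the scavenger receptor gene Msr1 rose 14.3-fold and Fcgr2b 11.5-fold. Of 12 antigen presentation genes 3 fell and 9 did not pass (3 adjusted over the list alone, adjusted p = 0.129); H2-DMa fell by 2.26 and Ifi30, a lysosomal thiol reductase gene, by 2.34. Neutrophil and granulocyte genes had 4 fallers and 6 others of 10 (4 adjusted over the list alone, adjusted p = 0.166), including S100a9, which fell by 1.93, and Mmp8, by 1.63. Lymphocyte genes had 1 faller and 8 others of 9 (1 adjusted over the list alone, adjusted p = 0.922), where the median was 0.23, the mean -0.10 and the test pointed up. Erythroid and mast cell genes counted 1 up and 5 neither of 6 (1 adjusted over the list alone, adjusted p = 0.483; median -0.05, mean 0.12, test up). Dendritic cell genes counted 1 down and 5 neither of 6 (1 adjusted over the list alone, adjusted p = 0.762). The labels of the resting cells name another CSF-1 source and no genotype. So any gene at either time, such as Ifi202b, Gdpd3 or stromal ones, may differ for reasons other than LPS.

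IL-10 added to LPS for 180 min raised P-selectin (Selp), the endothelial protein C receptor gene Procr, arginase 2 (Arg2), Il1rn and, mostly through IL-10-/- cells, Il4ra in the mean over the 3 genotypes. It lowered caveolin 1 (Cav1), the interferon-induced genes Mx1, Mx2, Rsad2, Ifit1 and Irf1, and the cytokine genes Il6 and, through IL-10-/- cells, Csf2. Metallothionein 1 (Mt1, mostly in IL-10-/-) and the glycolysis genes Pfkfb3, Ldha and Tpi1 rose, and the heat shock gene Hspa1b fell.

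In that mean 314 probe sets changed (168 higher, 146 lower; n = 2 per group, 1 for IL-6-/- with LPS alone). Selp rose 16.7-fold (4.06 ± 0.20, adjusted p = 8.97e-13), Procr 4.43-fold, Arg2 4.22-fold, Glipr2 3.86-fold, Chil1 3.77-fold and S100a8 3.75-fold (4.04e-05). Cav1 fell by 3.14 ± 0.15 (adjusted p = 8.97e-13), Mx1 by 2.49, Csf2 by 2.37, Ifit1 by 2.26, Rsad2 by 2.19 and Ifit2 by 2.17. The Csf2 mean came from IL-10-/- (6694 to 79.85), since signals were low in wild type (96.6 to 51.65) and IL-6-/- (65.8 to 13.5). Chil1 likewise rose mostly there (248.4 to 4119, against 1766 to 2141 in wild type). Il10 rose 1.94-fold (0.000415) and Stat3 1.86-fold (5.07e-06), and Il6 fell by 1.65 ± 0.33 (0.00298). Tnf fell by 0.94 (adjusted p = 0.0242) and Bcl3 rose by 0.71 (0.0344), wholly through IL-10-/- (668.7 to 3179; 3561 to 4227 in wild type, 4029 to 3390 in IL-6-/-). Each lost its call in 7 of the fits without 1 array, for example Tnf without wild-type LPS plus IL-10 replicate 1 (0.0686) and Bcl3 without wild-type LPS replicate 1 (0.13). Socs3 (0.31, adjusted p = 0.506), Il12b (-0.90, 0.0926), Il6ra (0.32), Il6st (0.40) and Il10ra (-0.17) did not pass. Il12b did pass over wild type and IL-10-/- alone (-1.43, 0.00915) and with a pseudocount of 200 (-0.84, 0.000575).

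Interferon response genes were the largest group lowered: 17 of 37 fell and 20 did not pass (25 fell and 1 rose adjusted over the list alone, list adjusted p = 1.24e-25), with Irf1 (-1.45) and Mx2 (-1.93) among them. STAT3-linked IL-10 targets had 8 up, 1 down and 10 neither of 19 (9 and 1 adjusted over the list alone, adjusted p = 7.82e-11), with Il1rn up 3.75-fold, Il4ra 3.10-fold and Dusp1 2.73-fold. Like Ptpn1, Mt1, Mt2 and Cebpd below, these means drew mostly on IL-10-/- (3065 to 34530, 1103 to 18970 and 1287 to 14920). Wild type gave 16340 to 34030, 13330 to 19400 and 8139 to 10410. Of 20 glycolysis and hypoxia genes 5 rose and 15 did not pass (7 adjusted over the list alone, adjusted p = 6.48e-08): Pfkfb3 2.22-fold, Bnip3 1.90-fold, Ldha 1.49-fold. Inflammatory cytokines had 4 fallers and 7 others of 11 (6 down and 2 up adjusted over the list alone, adjusted p = 1.1e-05). Chemokines had 5 down, 2 up and 9 neither of 16 (6 and 2 adjusted over the list alone, adjusted p = 0.0108, adjusted p = 0.111 with an estimated correlation). Ccl17 (-1.62), Ccl22 (-1.42) and Cxcl1 (-1.24) fell and Cxcl9 rose by 1.43. Ccl17 was low in wild type throughout (44 to 29.85), so its fall came from IL-10-/- (1364 to 31.85). Cytokine receptors, JAK, STAT and SOCS counted 5 up, 1 down and 23 neither of 29 (6 and 1 adjusted over the list alone, adjusted p = 0.0101, adjusted p = 0.111 with an estimated correlation). Ptpn1 rose 2.29-fold and Cish fell by 0.91. Erythroid and mast cell genes passed (0.00853, adjusted p = 0.101 with an estimated correlation) on 1 riser of 6, the carbonic anhydrase gene Car2 (2.43-fold), with 5 neither (2 adjusted over the list alone), but not without wild-type LPS replicate 1 (0.0527). Heat shock and stress genes had 2 up, 2 down and 23 neither of 27 (3 and 2 adjusted over the list alone, adjusted p = 0.659): Mt1 rose 2.47-fold and Mt2 1.83-fold, while Hspa1b fell by 1.55 and Hspa1a by 0.99. Immediate early genes (adjusted p = 0.0877) had 5 up, 1 down and 30 neither of 36 (5 and 1 adjusted over the list alone). Fos rose 1.92-fold and Cebpd 1.68-fold.

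In wild type alone, IL-10 at 180 min changed 11 probe sets (5 higher, 6 lower; n = 2 each), and 525 stood under 0.05 before adjustment. Selp rose from a mean signal of 1648 to 10690 (2.66 ± 0.32, adjusted p = 8.38e-05), the interferon-inducible chemokine gene Cxcl9 rose by 2.37 (8.53e-05), and Cav1 fell from 1663 to 268.4 (-2.42 ± 0.25, 6.68e-06). These 3 held whichever array was left out. Il1rn rose by 1.06 (0.00366), but not without LPS plus IL-10 replicate 2 (0.0861) or LPS replicate 1 (0.078), and Irf1 fell by 1.25 (0.00366) with the same losses (0.093 and 0.0966). The count was 17 without LPS plus IL-10 replicate 1, 3 without replicate 2, 3 without LPS replicate 1 and 6 without LPS replicate 2. Il10 (0.58), Il6 (-1.19), Socs3 (-0.10), Tnf (-0.32), Il12b (-0.27), Bcl3 (0.22), Stat3 (0.45), Il6ra (-0.00), Il6st (-0.38) and Il10ra (-0.12) did not pass.

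As a list, the interferon response fell in wild type (median -0.73, adjusted p = 4.97e-18, adjusted p = 0.126 with an estimated correlation), with 2 of 37 down and 35 neither (16 down and 1 up adjusted over the list alone). Glycolysis and hypoxia rose (0.000882) on 0 of 20 single calls (0 adjusted over the list alone), Ldha at 0.51 and Tpi1 at 0.45 having the smallest adjusted p. STAT3-linked IL-10 targets passed (0.0255, adjusted p = 0.126 with an estimated correlation) with 1 up and 18 neither of 19 (1 adjusted over the list alone), but not without LPS replicate 1 (0.216) or LPS plus IL-10 replicate 2 (0.324). Erythroid and mast cell genes (0.0255, adjusted p = 0.151 with an estimated correlation) had 0 of 6 called (1 adjusted over the list alone) and lost their call without the same arrays (0.505 and 0.324).

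In IL-10-/- cells IL-10 for 180 min changed 291 probe sets (187 higher, 104 lower; n = 2 each). Selp rose from 35.15 to 7956 (adjusted p = 6.38e-13), the heme-regulated repressor gene Bach1 27.3-fold (1.18e-11), Il4ra 16.6-fold, Chil1 14.2-fold, the adaptor gene Gab1 from 41.55 to 1086 and the lysosomal channel gene Mcoln2 11.4-fold. Csf2, which encodes GM-CSF, fell from 6694 to 79.85 (-5.70 ± 0.42, adjusted p = 1.03e-09), Cav1 by 4.39, Ccl17 by 4.13, Rsad2 by 3.07, Ccl22 by 2.87 and Cmpk2 by 2.87. Il12b fell by 2.58 (0.000679), Bcl3 rose 4.49-fold (4.89e-05), Stat3 2.88-fold (1.94e-06) and Il10 3-fold (0.00024). Il6 fell by 2.61 (0.00299), but not without LPS replicate 1 (0.0511), and Tnf fell by 1.84 (0.00446), but not without that array (0.0539) or LPS plus IL-10 replicate 2 (0.0517). Il6st rose by 1.15 (0.0101), a call lost without any 1 of the 4 arrays (for example 0.071 without LPS plus IL-10 replicate 1). Socs3 (0.78, adjusted p = 0.113), Il6ra (0.75) and Il10ra (-0.35) did not pass, though Socs3 did when blocked by replicate number (0.02) and with a pseudocount of 200, on another probe set (0.00431). The count was 187 without LPS plus IL-10 replicate 1, 176 without replicate 2, 187 without LPS replicate 1 and 185 without LPS replicate 2.

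STAT3-linked IL-10 targets rose in IL-10-/- (adjusted p = 1.2e-18), 10 of 19 up, 1 down and 8 neither (11 and 1 adjusted over the list alone), with Il1rn up 11.1-fold and Dusp1 11.2-fold. Cytokine receptors, JAK, STAT and SOCS rose too (4.21e-06; 7 up, 1 down, 21 neither of 29, or 10 and 1 adjusted over the list alone), as did glycolysis and hypoxia (1.57e-06; 3 up and 17 neither of 20, or 6 adjusted over the list alone). Ptpn1 rose 6.62-fold and Pfkfb3 3.69-fold. Inflammatory cytokines fell (1.57e-06; 5 down and 6 neither of 11, or 7 down and 2 up adjusted over the list alone), and so did chemokines (3.48e-05; 5 down and 11 neither of 16, or 6 down and 1 up adjusted over the list alone). Il1a stood at -1.57 and Cxcl1 at -1.99. The interferon response fell (3.12e-14, adjusted p = 0.121 with an estimated correlation), 13 of 37 down, 1 up and 23 neither (15 and 1 adjusted over the list alone). Irgm1 stood at -2.12 and Irf1 at -1.50, against a rise of Irf8 by 1.26. Immediate early genes rose (0.0157, adjusted p = 0.137 with an estimated correlation), 7 up, 2 down and 27 neither of 36 (8 and 2 adjusted over the list alone): Cebpd 3.84-fold, Fos 3.32-fold, Ier2 2.17-fold. Among heat shock and stress genes (0.75) Mt1 rose 6.92-fold and Mt2 4.47-fold. Hspa1b fell by 2.34 and Hspa1a by 1.95, with 23 neither of 27 (2 and 2 adjusted over the list alone). Inflammatory enzymes, receptors and costimulation (0.208) had 3 up, 2 down and 19 neither of 24 (4 and 3 adjusted over the list alone), with Procr up 9.90-fold.

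In IL-6-/- cells 17 probe sets changed with IL-10 at 180 min (11 higher, 6 lower; n = 2 against 1), and 499 stood under 0.05 before adjustment. Selp rose from 1553 to 12450 (2.96 ± 0.40, adjusted p = 0.000345) and Procr 3.74-fold (0.000345). The dimethylarginine hydrolase gene Ddah2 was called higher (0.00123), but this rested on the single LPS array, which gave 130.1 against group means of 546.2 to 992.6 everywhere else, so no rise with IL-10 is claimed. Cav1 fell from 2109 to 301.8 (-2.62, 6.98e-05) and Irf1 by 1.59 (0.00225). The count was 9 without LPS plus IL-10 replicate 1 and 5 without replicate 2. The interferon response fell (median -0.85, adjusted p = 1.19e-16, adjusted p = 0.236 with an estimated correlation), 1 of 37 down and 36 neither (9 down adjusted over the list alone). Glycolysis and hypoxia rose (0.00275) with 0 of 20 called (3 adjusted over the list alone), Bnip3 at 1.35 leading, but not without LPS plus IL-10 replicate 2 (0.0702). Il10 (0.70), Il6 (-1.14), Socs3 (0.25), Tnf (-0.66), Il12b (0.15), Bcl3 (-0.25), Stat3 (0.70), Il6ra (0.20), Il6st (0.43) and Il10ra (-0.05) did not pass.

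**Figure D2:**
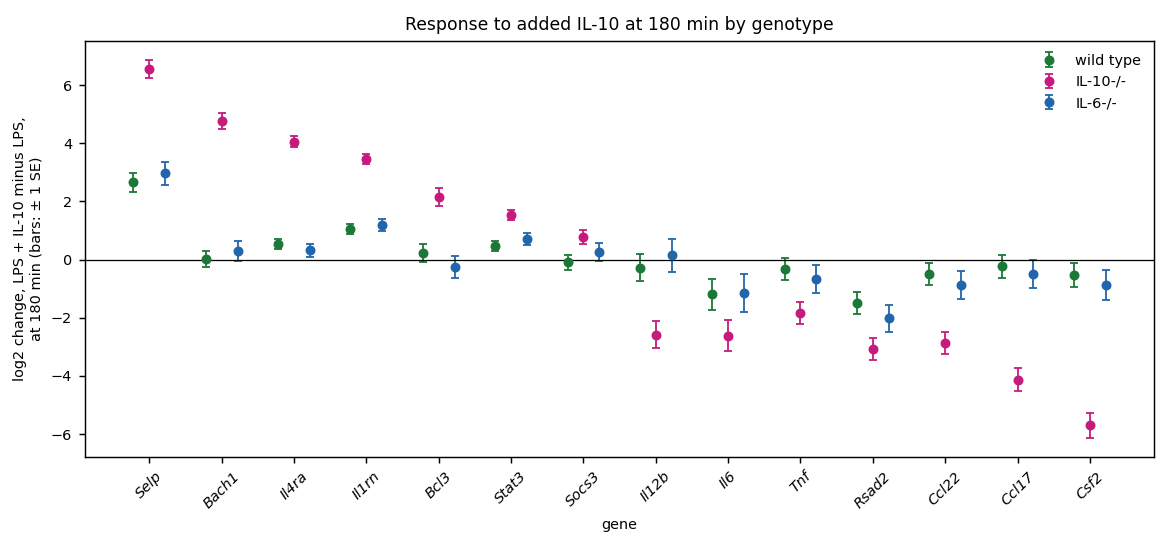
Log2 change with IL-10 added to LPS at 180 min in each genotype, with its standard error, for 14 genes.

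The response to IL-10 at 180 min differed between IL-10-/- and wild type for 46 probe sets (36 with a higher change in IL-10-/-, 10 with a lower one; n = 2 per group). Bach1 (4.76 ± 0.40, adjusted p = 5.89e-08), Chil1 (3.56), Il4ra (3.51 ± 0.26, 1.17e-08), Dusp1 (3.14), the sphingosine kinase gene Sphk1 (3.10), Mcoln2 (2.99), Il1rn (2.41, 1.45e-06) and the phosphatase gene Ptpn1 (2.19, 0.00283) rose more in the knockout. Csf2 (-5.16 ± 0.59, adjusted p = 1.34e-05), Ccl17 (-3.90) and the ganglioside synthase gene St3gal5 (-2.22, 0.00447) fell more. For Bach1 and Csf2 the genotypes stood apart with LPS alone: Bach1 gave 320.6 in IL-10-/- with LPS against 9804 in wild type, and 10080 against 9756 with IL-10. Csf2 gave 6694 against 96.6 with LPS alone. Bcl3 also rose more (1.94, adjusted p = 0.038), but not without, for example, wild-type LPS replicate 2 (0.242), and Stat3 (1.07, 0.0425) lost its call without any 1 of the 8 arrays (for example 0.207 without wild-type LPS replicate 1). Il10 (1.01), Il6 (-1.42), Socs3 (0.87), Tnf (-1.52), Il12b (-2.30), Il6ra (0.75), Il6st (1.53) and Il10ra (-0.23) did not pass. With a pseudocount of 200 Il12b (0.000591) and Il6st (0.0393) did, and Il6st also with a filter at 500 (0.0466). The count was 28 without IL-10-/- LPS plus IL-10 replicate 1 or replicate 2, or without IL-10-/- LPS replicate 1.

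Among the lists, STAT3-linked IL-10 targets rose more in IL-10-/- (adjusted p = 3.78e-16; 6 of 19 called, 13 neither, or 11 adjusted over the list alone). So did cytokine receptors, JAK, STAT and SOCS (1.01e-05; 3 of 29, 26 neither, or 4 adjusted over the list alone). Chemokines (5.71e-06; 3 of 16 lower, 13 neither, or 4 adjusted over the list alone) and inflammatory cytokines (0.000349; 1 of 11 lower, 10 neither, or 4 lower and 1 higher adjusted over the list alone) fell more.

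IL-10 acted on LPS-treated cells within 45 min, raising Selp, Il6, the growth-arrest gene Gadd45g, the kinase gene Map3k8, Saa3, and the transcription factor gene Nfil3 in the mean over genotypes. It lowered the nuclear receptor gene Nr4a1, Acod1, Ifrd1, Sgk1, Tnf and, mainly through the knockouts, Csf2. Il6 thus rose with IL-10 at 45 min and fell with it at 180 min.

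This mean held 85 changed probe sets (57 higher, 28 lower; n = 2 per group, 1 for IL-6-/- with LPS alone). Selp rose 15.3-fold (3.94 ± 0.20, adjusted p = 3.54e-12), Il6 12.3-fold (3.63 ± 0.33, 7.82e-08), Gadd45g 11.6-fold (6.77e-12), Map3k8 7.41-fold, Saa3 7.12-fold and Cxcl9 5.32-fold. Nr4a1 fell by 1.80 ± 0.17 (adjusted p = 8.8e-08), Csf2 by 1.78, Acod1 by 1.56, Ifrd1 by 1.55, Sgk1 by 1.44 and Tnf by 1.41 ± 0.24 (0.000898). Csf2 went from 410 to 26.05 in IL-10-/- and from 231.2, in a single array, to 24.4 in IL-6-/-, but was low throughout in wild type (52.9 to 8.45). Selp started from 32, 17.55 and 26.7 in wild type, IL-10-/- and IL-6-/-, so its folds at 45 min depend on the pseudocount. Socs3 rose 2.26-fold (3.19e-05). Il10 (0.11), Il12b (-0.11), Bcl3 (0.55, adjusted p = 0.427), Stat3 (0.22), Il6ra (-0.17), Il6st (0.36) and Il10ra (-0.31) did not pass, though Bcl3 did with arrays blocked by replicate number (0.62, 0.0397).

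STAT3-linked IL-10 targets rose (list adjusted p = 2.98e-19; 7 up, 12 neither of 19, or 9 up and 2 down adjusted over the list alone): Il1rn 3.97-fold, Il4ra 3.43-fold, Nfil3 4.72-fold. Cytokine receptors, JAK, STAT and SOCS rose (1.03e-05; 4 up, 25 neither of 29, or 7 adjusted over the list alone), with Cish up 2.04-fold and Ptpn1 1.90-fold. Chemokines rose (3.9e-05; 2 up, 1 down, 13 neither of 16, or 6 and 2 adjusted over the list alone), with Cxcl10 up 4.59-fold and Cxcl1 down by log2 -1.20. The interferon response rose (0.00272, adjusted p = 0.715 with an estimated correlation) on 1 of 37, Irf1 (1.90-fold), with 36 neither (5 adjusted over the list alone). Inflammatory cytokines had 1 up, 3 down and 7 neither of 11 (2 and 3 adjusted over the list alone, adjusted p = 0.621), where the median was -0.11, the mean 0.02 and the test pointed down. Il1a fell by 0.86. Inflammatory enzymes, receptors and costimulation had 4 up, 1 down and 19 neither of 24 (4 and 3 adjusted over the list alone, adjusted p = 0.12), with Procr up 3.06-fold. Of 36 immediate early genes 2 rose, 2 fell and 32 did not pass (2 and 4 adjusted over the list alone, adjusted p = 0.149), Cebpd rising 2.62-fold and Errfi1 1.65-fold. Of 27 heat shock and stress genes 2 rose, 1 fell and 24 did not pass (2 and 1 adjusted over the list alone, adjusted p = 0.615; median -0.06, mean 0.07, test up). Mt2 rose 4.08-fold and Mt1 3.16-fold, and Hspa1a fell by 0.90.

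Selp, Gadd45g and Map3k8 rose in each genotype on its own at 45 min. In wild type 33 probe sets changed (23 higher, 10 lower, n = 2 each), 19 without LPS plus IL-10 replicate 1 and 17 without replicate 2. Selp (3.74 ± 0.32, adjusted p = 2.57e-07), Gadd45g (3.42), Map3k8 (2.74), Cxcl9 (1.93), Il4ra (1.92), Nfil3 (1.70), Il1rn (1.60) and Procr (1.53) rose. Acod1 (-2.07), Nr4a1 (-1.76), Ifrd1 (-1.74) and Sgk1 (-1.49) fell. Il6 rose by 3.20 (0.00174), but not without LPS plus IL-10 replicate 1 (0.057). Tnf fell by 1.77 (0.037), a call lost without any 1 of the 4 arrays (0.352, 0.228, 0.229 and 0.295). STAT3-linked IL-10 targets rose (3.94e-12; 5 up, 14 neither of 19, or 7 adjusted over the list alone). Chemokines (0.00706; 2 up, 14 neither of 16, or 2 up and 1 down adjusted over the list alone), cytokine receptors, JAK, STAT and SOCS (0.00706; 1 up, 28 neither of 29, or 4 adjusted over the list alone) and the interferon response (0.00706; 1 up, 36 neither of 37, or 1 adjusted over the list alone) passed (with an estimated correlation adjusted p = 0.16, 0.16 and 0.751). Without LPS replicate 1 they had 0.0899, 0.0794 and 0.0794. Chemokines (0.0613) and the interferon response (0.056) also lost the call without LPS plus IL-10 replicate 1, and the receptors without replicate 2 (0.139). Socs3 (1.05, adjusted p = 0.0798), Il10 (0.02), Il12b (-0.43), Bcl3 (0.83), Stat3 (0.27), Il6ra (-0.24), Il6st (0.31) and Il10ra (-0.49) did not pass. Socs3 did when blocked by replicate number (0.00796) and with a pseudocount of 200, where another probe set stands for it (1.24, 0.00031).

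In IL-10-/- IL-10 changed 45 probe sets at 45 min (34 higher, 11 lower; n = 2 each), falling to 26 and 29 without LPS plus IL-10 replicates 1 and 2 and to 25 and 28 without LPS replicates 1 and 2. Il6 rose 17.8-fold (4.16 ± 0.53, adjusted p = 4.56e-05), Selp 16.3-fold, Gadd45g 8.71-fold, Map3k8 8.25-fold, Cxcl9 6.32-fold, Nfil3 5.70-fold, Cxcl10 5.54-fold and Il1rn 4.93-fold. Csf2 fell by 2.60 (0.000891), Nr4a1 by 1.85 and Sgk1 by 1.57. Socs3 rose 2.29-fold (0.0185), but not without LPS plus IL-10 replicate 1 (0.389) or 2 (0.0662) or LPS replicate 2 (0.814). Mt1 rose 3.15-fold, Mt2 4.11-fold, Procr 2.85-fold and Cebpd 3.28-fold. STAT3-linked IL-10 targets rose (2.79e-16; 6 up, 13 neither of 19, or 8 up and 1 down adjusted over the list alone). Chemokines (0.00201; 2 up, 14 neither of 16, or 4 up and 1 down adjusted over the list alone, adjusted p = 0.108 with an estimated correlation; 0.0559 without LPS replicate 1) and cytokine receptors, JAK, STAT and SOCS (0.0073; 3 up, 26 neither of 29, or 6 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation; 0.118 without LPS plus IL-10 replicate 1) rose as well. The rise of inflammatory enzymes, receptors and costimulation (0.0281; 3 up, 1 down, 20 neither of 24, or 6 and 2 adjusted over the list alone) rested on LPS plus IL-10 replicate 1, without which the median was -0.04 (adjusted p = 0.567), and on LPS replicate 2 (0.102). It had adjusted p = 0.237 with an estimated correlation. Tnf (-1.30, adjusted p = 0.296), Il10 (0.61), Il12b (0.54), Bcl3 (0.58), Stat3 (0.16), Il6ra (0.19), Il6st (0.71) and Il10ra (-0.25) did not pass, though Tnf did with a pseudocount of 200 (0.0123).

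In IL-6-/- 27 probe sets changed (21 higher, 6 lower; n = 2 against 1), 11 without LPS plus IL-10 replicate 1 and 14 without replicate 2. Gadd45g rose 16.7-fold (4.06 ± 0.38, adjusted p = 1.5e-06), Selp 16.5-fold, Map3k8 7.38-fold, Cxcl9 6.23-fold, Nfil3 5.69-fold, Il1rn 4.2-fold and Il4ra 3.56-fold, and Rhob fell by 1.53. Il6 rose by 3.52 (0.00805), but not without LPS plus IL-10 replicate 1 (0.0954). STAT3-linked IL-10 targets (5.84e-14; 5 up, 14 neither of 19, or 7 adjusted over the list alone) and cytokine receptors, JAK, STAT and SOCS (1.7e-05; 2 up, 27 neither of 29, or 3 adjusted over the list alone) rose. Chemokines rose (0.00259; 1 up, 15 neither of 16, or 2 up and 1 down adjusted over the list alone, adjusted p = 0.0954 with an estimated correlation), and so did the interferon response (0.00259; 0 of 37 called, or 0 adjusted over the list alone, adjusted p = 0.824 with an estimated correlation). Without LPS plus IL-10 replicate 1 they had 0.0636 and 0.231. The interferon response also lost its call with arrays blocked by replicate number (0.0721). Socs3 (1.28, adjusted p = 0.0981), Tnf (-1.16), Il10 (-0.29), Il12b (-0.44), Bcl3 (0.23), Stat3 (0.23), Il6ra (-0.46), Il6st (0.07) and Il10ra (-0.19) did not pass, though Socs3 did with a pseudocount of 200, on another probe set (0.00263).

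IL-6 added to LPS for 45 min raised Selp, Map3k8, Il6, Saa3, Nfil3, Sphk1, Gadd45g and Il4ra in the mean over the 3 genotypes, genes that IL-10 raised as well. Of 45 changed probe sets (44 higher, 1 lower; n = 2 per group, 1 for IL-6-/- with LPS alone), 40 were also raised by IL-10, where 0.305 would be expected of independent lists. Both changes are measured from the same LPS arrays. Selp rose 5.73-fold (2.52 ± 0.20, adjusted p = 1.39e-08), Map3k8 4.76-fold, Il6 4.56-fold (2.19 ± 0.33, 0.000552), Saa3 4.5-fold, Nfil3 4.32-fold, Sphk1 4.17-fold and Socs3 1.82-fold (0.00546; 0.101 over wild type and IL-10-/- alone). The 1 lower probe set stood for Sgk1 (-0.57, adjusted p = 0.0117), a call lost without, for example, wild-type LPS plus IL-6 replicate 2 (0.0542). Tnf (-0.37, adjusted p = 1), Il10 (0.38), Il12b (-0.37), Bcl3 (0.40), Stat3 (0.22), Il6ra (-0.27), Il6st (0.30) and Il10ra (-0.17) did not pass.

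STAT3-linked IL-10 targets rose with IL-6 (list adjusted p = 1.25e-16; 6 up, 13 neither of 19, or 9 up and 1 down adjusted over the list alone): Gadd45g 3.52-fold, Il4ra 2.79-fold, Il1rn 2.05-fold. Chemokines (7.82e-05; 2 up, 14 neither of 16, or 4 adjusted over the list alone) rose through Cxcl9 (2.58-fold) and Cxcl10 (2.63-fold), and cytokine receptors, JAK, STAT and SOCS rose (8.84e-05; 3 up, 26 neither of 29, or 5 adjusted over the list alone). Inflammatory enzymes, receptors and costimulation rose (0.00207; 4 up, 20 neither of 24, or 6 up and 1 down adjusted over the list alone, adjusted p = 0.0733 with an estimated correlation), with a median of -0.05, a mean of 0.18 and the test up. Procr rose 1.78-fold. The interferon response (0.00308; 1 up, 36 neither of 37, or 4 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), with Irf1 up 1.77-fold, and heat shock and stress genes (0.00308; 2 up, 25 neither of 27, or 2 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation), with Mt2 up 2.67-fold and Mt1 2.17-fold, passed too. The interferon response no longer passed for IL-6 over wild type and IL-10-/- alone (0.207), nor did it for IL-10 (0.0854). Of 36 immediate early genes 3 rose, 1 fell and 32 did not pass (3 and 2 adjusted over the list alone, adjusted p = 0.403), Cebpd rising 2.02-fold and Errfi1 1.67-fold.

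By genotype, IL-6 changed 18 probe sets in wild type (15 higher, 3 lower; n = 2 each), with 6 and 9 without LPS plus IL-6 replicates 1 and 2 and 11 and 6 without LPS replicates 1 and 2. Selp (3.05 ± 0.32, adjusted p = 6.92e-06), Map3k8 (2.44), Sphk1 (2.29), Nfil3 (2.28), Il4ra (1.87) and Il1rn (1.37) held in every one of these fits. Among lists, STAT3-linked IL-10 targets rose (2.11e-11; 4 up, 15 neither of 19, or 8 adjusted over the list alone). Chemokines (0.000263; 1 up, 15 neither of 16, or 4 adjusted over the list alone), inflammatory enzymes, receptors and costimulation (8.85e-05; 2 up, 22 neither of 24, or 6 adjusted over the list alone) and cytokine receptors, JAK, STAT and SOCS (0.00076; 1 up, 28 neither of 29, or 1 adjusted over the list alone) rose. NF-kappaB components and feedback rose (0.0004; 1 up, 26 neither of 27, or 3 adjusted over the list alone), though not without LPS replicate 1 (0.0833). The interferon response (0.0324; 1 up, 36 neither of 37, or 1 adjusted over the list alone, adjusted p = 0.664 with an estimated correlation) and heat shock and stress genes (0.0148; 2 up, 25 neither of 27, or 2 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation) rose too. Dendritic cell genes fell (0.0124; 0 of 6 called, or 1 down adjusted over the list alone, adjusted p = 0.114 with an estimated correlation). In this order, these 3 lists had 0.125, 0.0808 and 0.125 without LPS replicate 1 and 0.149, 0.217 and 0.176 without LPS plus IL-6 replicate 1. Heat shock and stress genes had 0.226 after quantile normalization. Il6 (2.18, adjusted p = 0.122), Socs3 (0.67), Tnf (-0.10), Il10 (0.58), Il12b (-0.96), Bcl3 (0.64), Stat3 (0.44), Il6ra (-0.11), Il6st (0.64) and Il10ra (-0.08) did not pass. With a pseudocount of 200 Il6 (0.0412) and another Socs3 probe set (0.0153) did.

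In IL-10-/- IL-6 raised 3 probe sets and lowered 0 (n = 2 each; 171 under 0.05 before adjustment), for Map3k8 (2.05 ± 0.29, adjusted p = 0.00126), Nfil3 (1.91) and Il4ra (1.06). The count was 0 without LPS plus IL-6 replicate 1 or without LPS replicate 2, where Map3k8 had 0.0822 and 0.0569. Of the lists, only STAT3-linked IL-10 targets passed, and rose (1.76e-07; 2 up, 17 neither of 19, or 5 up and 1 down adjusted over the list alone). In IL-6-/- 6 probe sets rose and 0 fell (n = 2 against 1; 188 under 0.05 before adjustment). Selp (2.99 ± 0.40, adjusted p = 0.00076) and Il4ra (1.51, 0.00255) held throughout. Gadd45g (2.33), Map3k8 (2.27), Nfil3 (2.15) and Sphk1 (2.15) did not pass without LPS plus IL-6 replicate 1 (0.103, 0.0819, 0.0633 and 0.816), when the count was 2. Sphk1 also lost its call when blocked by replicate number (0.168). STAT3-linked IL-10 targets (4.23e-10; 3 up, 16 neither of 19, or 6 adjusted over the list alone) rose there. So did chemokines (0.00085; 0 of 16 called, or 2 adjusted over the list alone), cytokine receptors, JAK, STAT and SOCS (0.00398; 1 up, 28 neither of 29, or 3 adjusted over the list alone) and the interferon response (0.000829; 0 of 37, or 0 adjusted over the list alone), each lost with an estimated correlation (adjusted p = 0.09, 0.131 and 0.622). In IL-10-/- and IL-6-/- in turn, none of the following passed: Il6 changed by 2.07 and 2.31, Socs3 by 0.78 and 1.16, Tnf by -0.55 and -0.46, Il10 by 0.40 and 0.17, Il12b by 0.93 and -1.07, Bcl3 by 0.37 and 0.17, Stat3 by 0.09 and 0.14, Il6ra by -0.23 and -0.47, Il6st by 0.57 and -0.30, and Il10ra by -0.15 and -0.27.

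IL-10 and IL-6 differed in strength on some genes at 45 min. Gadd45g, Selp, Cxcl9, Il1rn and Procr were higher with IL-10, and Nr4a1, Acod1, Ifrd1, Rhob and Sgk1 lower. There were 18 probe sets (6 higher and 12 lower with IL-10; n = 2 per group). The excess of lower calls did not hold, with 7 and 9 after quantile normalization, 7 and 5 over wild type and IL-10-/- alone, and 6 and 5 without wild-type LPS plus IL-6 replicate 1. Gadd45g differed by 1.72 ± 0.18 (adjusted p = 6.37e-06), Selp by 1.42, Cxcl9 by 1.04, Il1rn by 0.96 and Procr by 0.78. Nr4a1 stood at -1.25 ± 0.15 (3.76e-05), Acod1 at -1.18, Ifrd1 at -1.17, Rhob at -1.05 and Sgk1 at -0.87. Il6 was higher with IL-10 (1.44, adjusted p = 0.0476) and Tnf lower (-1.04, 0.0498), but both lost their call in most fits without 1 array, for example without wild-type LPS plus IL-10 replicate 1 (0.195 and 0.18). Tnf also lost it when blocked by replicate number (0.109). The count was 11 without that array, 10 without its replicate 2, and 11 without IL-10-/- LPS plus IL-10 replicate 2, wild-type LPS plus IL-6 replicate 1 or IL-6-/- LPS plus IL-6 replicate 1. STAT3-linked IL-10 targets were higher with IL-10 (9.51e-05; 2 up, 17 neither of 19, or 5 adjusted over the list alone). Immediate early genes (9.73e-05; 2 down, 34 neither of 36, or 2 adjusted over the list alone) and NF-kappaB components and feedback (0.00612; 1 down, 26 neither of 27, or 1 and 1 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation) were lower. Socs3 (0.31), Il10 (-0.27), Il12b (0.26), Bcl3 (0.15), Stat3 (-0.00), Il6ra (0.10), Il6st (0.06) and Il10ra (-0.14) did not pass.

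Under LPS for 180 min, IL-10-/- cells held more Csf2, Ccl17, Cited2, Ly9 and F11r transcript than wild type, and far less Bach1, Selp, Il4ra, Mcoln2, Batf and Il1rn. Metallothioneins Mt1 and Mt2, Dusp1, Ptpn1, Cebpd and Bcl3 were lower too. Adding IL-10 reversed many of these differences: 45 probe sets were both higher in IL-10-/- and lowered there by IL-10, and 115 were lower and raised (1.05 and 3.48 expected of independent lists). The 2 comparisons share the IL-10-/- LPS arrays (correlation of the changes -0.67, against -0.50 simulated without any effect); with a different replicate in each it was -0.394 and -0.395.

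There were 236 changed probe sets (83 higher, 153 lower; n = 2 each), 131 and 127 without IL-10-/- LPS replicates 1 and 2 and 105 without wild-type LPS replicate 2. Csf2 (6694 against 96.6, adjusted p = 2.44e-09) and Ccl17 (1364 against 44, 4.45e-07) were higher. Their wild-type signals were too low for an exact fold, with log2 differences of 4.54 and 2.68 at a pseudocount of 200 and 5.98 and 4.67 at 10. Cited2 was higher 6.70-fold, Ly9 6.02-fold and F11r, which encodes a junctional adhesion molecule, 5.32-fold. Bach1 was lower by 4.71 ± 0.28 (adjusted p = 2.36e-11). Selp gave 35.15 against 1648, and Il4ra stood at -3.54, Mcoln2 at -3.37, Batf at -2.99 and Bcl3 at -2.30 (3.37e-05). Il6 was 6.83-fold higher (0.00249), but not without wild-type LPS replicate 2 (0.0796). Il12b was 4.03-fold (0.0113) and Tnf 2.96-fold higher (0.0224), yet neither passed without any 1 of the 4 arrays (Il12b 0.0902, 0.103, 0.0666 and 0.119; Tnf 0.165, 0.123, 0.143 and 0.112). Socs3 (-1.04, adjusted p = 0.0192) was lost without IL-10-/- LPS replicate 2 (0.303) and both wild-type LPS replicates (0.0717 and 0.189), and the Il10 probe set (-0.94, 0.0464) without each array (0.21, 0.238, 0.26 and 0.121).

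STAT3-linked IL-10 targets were lower in IL-10-/- (list adjusted p = 2.93e-15; 11 down, 1 up, 7 neither of 19, or 12 and 1 adjusted over the list alone). Il1rn stood at -2.40 and Dusp1 at -2.62. Also lower were cytokine receptors, JAK, STAT and SOCS (1.02e-05; 7 down, 1 up, 21 neither of 29, or 7 and 1 adjusted over the list alone), with Ptpn1 at -2.23 and Stat3 at -1.05. Chemokines (5.58e-07; 4 up, 12 neither of 16, or 8 adjusted over the list alone) and inflammatory cytokines (8.93e-06; 5 up, 1 down, 5 neither of 11, or 5 and 2 adjusted over the list alone) were higher. The others did not pass. Interferon response genes (0.771) had 1 up, 2 down and 34 neither of 37 (3 and 2 adjusted over the list alone), with Irf8 at -1.51. Immediate early genes (0.338) had 1 up, 6 down and 29 neither of 36 (3 and 7 adjusted over the list alone), with Cebpd at -1.99. Heat shock and stress genes (0.762) had 2 up, 2 down and 23 neither of 27 (4 and 2 adjusted over the list alone), with Mt1 at -2.33, Mt2 at -1.98 and Hspa1a 3.61-fold higher. Glycolysis and hypoxia (0.158) had 3 down and 17 neither of 20 (4 adjusted over the list alone). Ifi202b was lower by far (31.85 against 7504, adjusted p = 3.71e-13), with a size set by the pseudocount (-5.06 with 200, -7.73 with 10). It was low in IL-10-/- under every condition, with a mean signal of 23.91 against 3320 in wild type, and so were Gdpd3 (204.3 against 1168) and Erdr1 (890.3 against 4889).

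**Figure D3:**
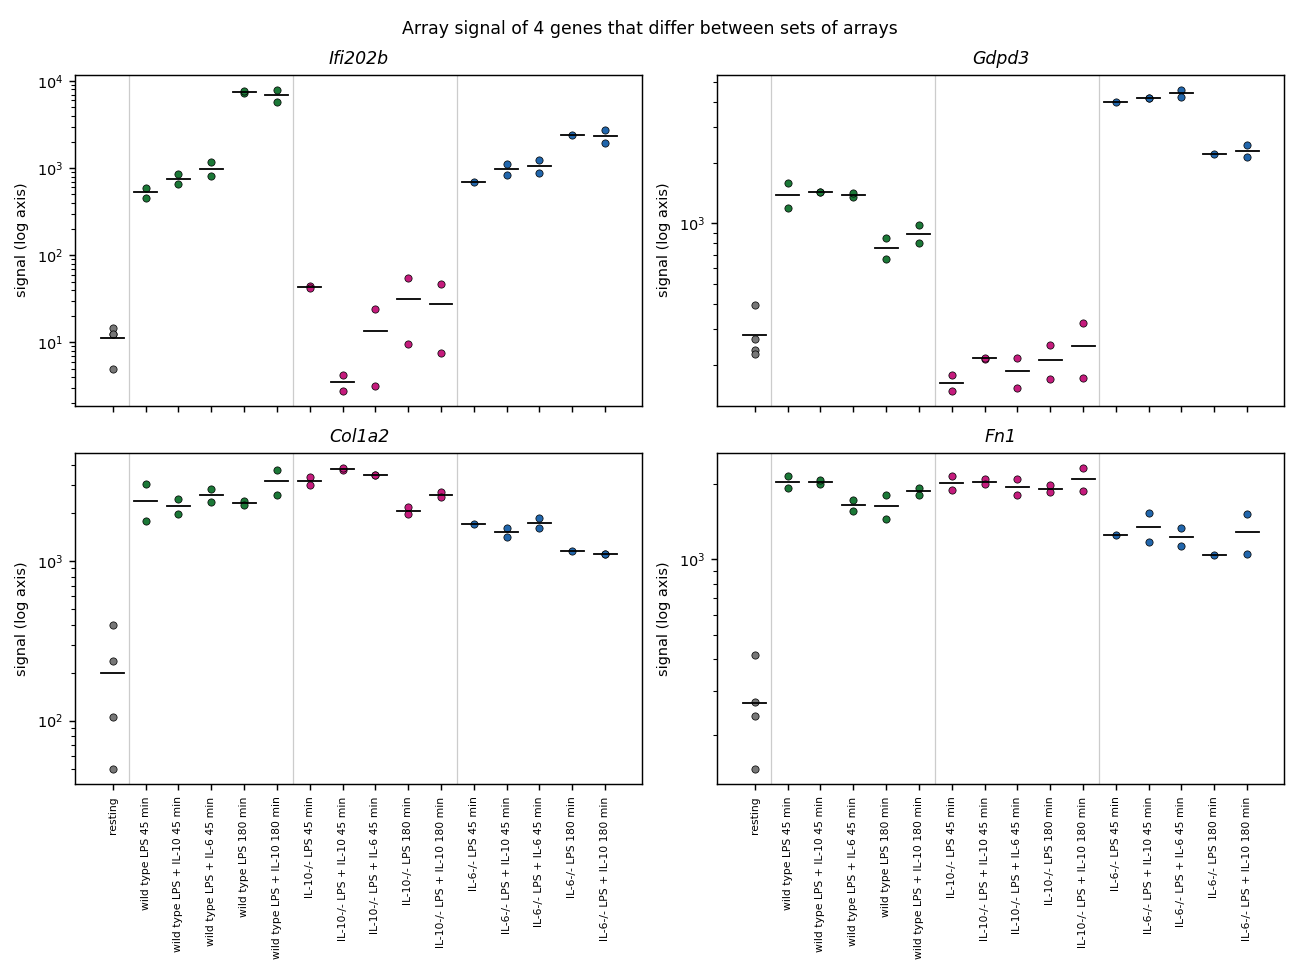
Signal of Ifi202b, Gdpd3, Col1a2 and Fn1 in each array, by group.

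At 45 min of LPS, IL-10-/- differed from wild type in 31 probe sets (23 higher, 8 lower; n = 2 each). There were 9 (4 higher, 5 lower) and 6 (2 higher, 4 lower) without IL-10-/- LPS replicates 1 and 2, so the excess of higher calls did not hold. Without wild-type LPS replicates 1 and 2 there were 10 each (7 and 6 higher). The glycerophosphodiesterase gene Gdpd3 (-2.74 ± 0.25, adjusted p = 1.06e-06), Ifi202b (-2.62, 3.95e-05) and Erdr1 (-1.98, 0.000129) were lower in all these fits. The Il10 probe set was higher (1.28, adjusted p = 0.0191), but without each array in turn had 0.216, 0.145, 0.239 and 0.13, and Csf2 (2.16, 0.0137) 0.202, 0.11, 0.099 and 0.177. Complement gene C1qa was 2.59-fold higher (0.00173), though not without IL-10-/- replicate 2 (0.109) or wild-type replicate 1 (0.099). Il6 (-0.21), Socs3 (-0.03), Tnf (0.38), Il12b (-0.90) and Bcl3 (0.42) did not pass.

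Macrophage identity (adjusted p = 0.000104; 2 up, 26 neither of 28, or 6 adjusted over the list alone), NF-kappaB components and feedback (0.000285; 0 of 27 called, or 0 adjusted over the list alone) and inflammatory enzymes, receptors and costimulation (0.00308; 1 up, 23 neither of 24, or 3 adjusted over the list alone, adjusted p = 0.0614 with an estimated correlation) were higher at 45 min in IL-10-/-. Glycolysis and hypoxia (0.00531; 0 of 20 called, or 0 adjusted over the list alone) and STAT3-linked IL-10 targets (0.00707; 2 up, 17 neither of 19, or 3 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation) were higher as well. So were the interferon response (0.0263; 1 down, 36 neither of 37, or 1 and 1 adjusted over the list alone, adjusted p = 0.567 with an estimated correlation) and inflammatory cytokines (0.0394; 1 up, 10 neither of 11, or 2 adjusted over the list alone, adjusted p = 0.08 with an estimated correlation). Without IL-10-/- LPS replicate 2 these 4 lists had 0.0542, 0.0542, 0.0592 and 0.149. Inflammatory cytokines also lost their call after quantile normalization (0.138), blocked by replicate number (0.0664) and without wild-type LPS replicates 1 (0.0644) and 2 (0.122), and the interferon response without the same arrays (0.102 and 0.0642). Lymphocyte (0.0121; 0 of 9 called, or 0 adjusted over the list alone) and dendritic cell genes (0.0223; 0 of 6, or 0 adjusted over the list alone) were lower, each lost with an estimated correlation (adjusted p = 0.124 and 0.124) and without IL-10-/- LPS replicate 2 (0.0555 and 0.0542). Lymphocyte genes also lost it without wild-type LPS replicate 2 (0.116), and dendritic cell genes without wild-type replicate 1 (0.134) and after quantile normalization (0.0676).

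IL-6-/- cells under LPS for 180 min differed from wild type in 15 probe sets (3 higher, 12 lower; n = 1 against 2), 7 and 8 without wild-type LPS replicates 1 and 2. The chitinase-like gene Chil1 (-4.76 ± 0.43, adjusted p = 5.85e-07) was lower, and the integrin gene Itgax was 4.06-fold higher (0.00492), though not without wild-type LPS replicate 1 (0.0509). Chil1 gave 16.9 in the single IL-6-/- array, against 1766 in wild type, and 160.3 against 2141 with IL-10. The phospholipase gene Pla2g12a (-2.69, 0.00154) and Ddah2 (-2.05, 0.00182) were called lower on that array alone. It gave 42.2 for Pla2g12a and 130.1 for Ddah2, where the other IL-6-/- groups gave 241.3 to 352.8 and 743 to 927.6, so neither call can be put down to the genotype. Il10 (-0.80), Il6 (-1.73, adjusted p = 0.485), Socs3 (-0.38), Tnf (0.61), Il12b (-1.17) and Bcl3 (0.21) did not pass, and no list passed.

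At 45 min limma called 0 probe sets between IL-6-/- and wild type, with 419 under 0.05 before adjustment (n = 1 against 2); without wild-type LPS replicate 1 the count was 1. Msr1 (1.45, adjusted p = 0.165) and C1qb (0.75, 0.257) came closest among the named genes. Il10 (-0.32), Il6 (1.33, adjusted p = 0.975), Socs3 (-0.18), Tnf (0.37), Il12b (0.07) and Bcl3 (0.54) did not pass. Of the lists, stromal genes were lower (0.00752; 0 of 12 called, or 0 adjusted over the list alone, adjusted p = 0.577 with an estimated correlation) and macrophage identity higher (0.0124; 0 of 28, or 2 adjusted over the list alone, adjusted p = 0.278 with an estimated correlation), both lost without wild-type LPS replicate 2 (0.0579 and 0.108). NF-kappaB components and feedback were higher (0.0231; 0 of 27, or 0 adjusted over the list alone, adjusted p = 0.278 with an estimated correlation), but not without wild-type LPS replicate 1 (0.397) or after quantile normalization (0.0654). Interferon response genes were lower (0.0483; 0 of 37, or 0 adjusted over the list alone, adjusted p = 0.656 with an estimated correlation), but not without either wild-type array (0.123 and 0.118) or after quantile normalization (0.0992). Blocked by replicate number, stromal genes had 0.0712, NF-kappaB components and feedback 0.0766 and the interferon response 0.363.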

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

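The tests of other resting cultures, of a rise with time, of missing IL-10 and of shared arrays behind the genes raised by both cytokines were chosen only after those results were seen.

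All 12 stromal genes tested, of 14 on the array, stood above resting at both times. If resting cells came from other cultures, the genes should differ little between 45 and 180 min of LPS, whereas a response to LPS should grow. The median of the wild-type difference, 180 minus 45 min, was -0.121, which fits other cultures and excludes a rise with time, though not a rise complete within 45 min. Scaling was excluded, as quantile normalization kept 100% of the median at 180 min. None of the stromal genes is in another list, and macrophages themselves make Fn1.

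The genes that differed between IL-10-/- and wild type under LPS at 180 min may reflect missing IL-10 or genetic background, which was tested only around the deleted gene. For 63 probe sets called on replicate 1 alone, the difference in replicate 2 was 1.91, and 0.322 once both genotypes received IL-10; that is 16.8%, which fits missing IL-10. A lasting offset in all 5 conditions held for 17 probe sets of 9 genes (Cd5l, Lpl, Erdr1, Folr2, Gdpd3, Cap1, Ifi202b, Cdkn1c and Npl), 11 of them among the 236 called. Only Npl lay among the 200 tested neighbours of Il10, against 8 of 5863 other genes (Fisher's exact test p = 0.261, one-sided). Npl gave 365.4 in wild type, 61.95 in IL-10-/-, 108.4 in IL-6-/- and 134.8 in resting cells, so it was not low in the Il10 knockout alone. Strain background near Il10 stays open.

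IL-10 and IL-6 resembled each other at 45 min. Over all probe sets their changes correlated at 0.668, against 0.571 simulated with no effect, and without shared arrays the covariance was 21% of that within genotypes, so shared LPS arrays fit most of the resemblance of the whole profile. They are excluded for the genes raised by both: the probe sets IL-10 raised in 1 genotype had a median IL-6 change of 1.08 in the other genotypes. A later harvest stays open: genes rising with time exceeded those falling by 0.0105 for IL-10 and -0.0156 for IL-6, but IL-10 lowers some risers. That STAT3, which both receptors activate, raises these genes was not tested.

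Random assignment of arrays to arms was tested with 100 splits within genotypes. For IL-10 at 180 min, IL-10 at 45 min and IL-6 at 45 min only 1, the real split, reached the count found, and the highest others (188, 57 and 17) exchanged a single IL-6-/- array. For IL-10 against IL-6 2 of 100 did, and the highest other (45) parted replicate 1 from replicate 2 in both knockouts, so replicate number matters there; blocked by it the count was 19.

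The IL-10 response at 180 min differed between IL-10-/- and wild type for 46 probe sets, a difference between groups. Its 42 genes included Bach1 (4.76), Chil1 (3.56), Il4ra (3.51), Dusp1 (3.14), Sphk1 (3.10), Mcoln2 (2.99), Il1rn (2.41), Ptpn1 (2.195), Bcl3 (1.94), Stat3 (1.07), Csf2 (-5.16), Ccl17 (-3.90), Pofut2 (-3.44), Ccl22 (-2.37), Cited2 (-2.30), St3gal5 (-2.22) and Cxcl9 (-1.80). Many of these genes already differed between the genotypes with LPS alone. Pofut2, Ccl22, Cited2 and Cxcl9 each lost the call without some arrays, for example without IL-10-/- LPS replicate 1 (adjusted p = 0.17, 0.113, 0.0586 and 0.174).

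Single resting arrays stood far from the other 3 for 6 of 105 genes, where 5.25 would be expected by chance: Icam1 (865.6), Il6 (223.8), Jak2 (303.8) and Tnip1 (1735) in replicate 4, and Tpi1 (5692) and Hif1a (5332) in replicate 2. A control probe set for Il10, left out of the tests, gave its highest means in IL-10-/- at 45 min with LPS and IL-6 (2894) and with LPS and IL-10 (2890), against 363.9 (SD 47.6, n = 4) in resting cells.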

How the results depend on the processing

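The settings below other than leaving out resting replicate 4 were fixed before the data were seen. Counts of changed probe sets kept within 1.5 times of those reported for most settings, and the cause of the moves below was not tested, except that leaving out an array removes replicates.

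Of 751 gene results, 705 kept their call without an intensity trend, 710 with a pseudocount of 200, 714 with one of 10, 722 without a filter and 728 after quantile normalization; 707 of 714 did so with a filter at 500. Of 4164 gene results with 1 array left out, 3736 kept theirs, as did 534 of 580 list results. With an estimated correlation 59 of 104 list calls held and 45 were lost. One result reversed: Mpo after 180 min of LPS was 0.31 (adjusted p = 0.557) without a filter, where another probe set stands for the gene, against -1.05.

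A pseudocount of 200 moved the count for IL-10 at 180 min in IL-6-/- to 27, for IL-6-/- against wild type at 45 min to 2 and for the difference of the IL-10 response to 72. Without a filter IL-10 at 180 min in IL-6-/- gave 7; after quantile normalization IL-6-/- against wild type at 45 min gave 1; without a trend IL-10 against IL-6 gave 11; and over wild type and IL-10-/- alone IL-6 at 45 min gave 26. Leaving out resting replicate 4, chosen after the data were seen, gave 17 for IL-10 at 180 min in wild type, 7 for IL-6 in IL-10-/-, 32 for IL-10 at 180 min in IL-6-/-, and 2 and 25 for IL-6-/- against wild type at 45 and 180 min. The gains elsewhere were smaller as ratios, though not always in number: 340 for IL-10 at 180 min in IL-10-/-, 58 and 34 for IL-10 at 45 min in IL-10-/- and IL-6-/-, 22 for IL-10 against IL-6, 34 and 292 for IL-10-/- against wild type at 45 and 180 min, and 65 for the difference of the IL-10 response. That array is in none of these comparisons, so it acts on these counts through the variance alone. For Socs3, leaving it out or adding 200 also changed which probe set stands for the gene.

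Blocking by replicate number kept all 20 counts within 1.5 times: for example 1647 and 2951 for LPS at 45 and 180 min, 342 for IL-10 at 180 min over the genotypes and 53 for the difference of the IL-10 response. The pairing lost 19 and gained 6 of 751 gene calls and lost 5 of 104 list calls.

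With 1 array left out, the counts ranged from 695 to 1482 (LPS at 45 min), 3 to 17, 176 to 187 and 5 to 9 (IL-10 at 180 min in wild type, IL-10-/- and IL-6-/-), 17 to 23, 25 to 29 and 11 to 14 (IL-10 at 45 min, same order), and 6 to 11, 0 to 3 and 2 to 7 (IL-6 at 45 min, same order). They ranged from 10 to 18 for IL-10 against IL-6, 6 to 10 and 105 to 164 for IL-10-/- against wild type at 45 and 180 min, 0 to 1 and 7 to 8 for IL-6-/- against wild type, and 28 to 44 for the difference of the IL-10 response. The means over genotypes ranged from 239 to 274, 74 to 85 and 32 to 39. In all, 45 of 104 such counts moved by over 1.5 times. Groups of 2 arrays limit what can be called, and signals near background limit low genes.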

Other observations

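None of the values in this part comes from a test, and all were looked at after the results were seen. For some genes IL-10 and LPS alone differed at 45 min and hardly at 180 min. In wild type Gadd45g gave a mean signal of 4642 with LPS and IL-10 at 45 min and 294.2 at 180 min, and 410.2 and 376.7 with LPS alone. Nfil3 gave 1134 and 557.5 with IL-10, and 316.1 and 573.2 with LPS alone. Others differed at both times: Selp gave 1044 and 10690 with IL-10, and 32 and 1648 with LPS alone. Il1rn gave 3264 and 34030 with IL-10, and 1045 and 16340 with LPS alone, so both were higher at 180 min without added IL-10 as well. In IL-10-/- with LPS alone Selp gave 17.55 and 35.15, and Il1rn 1296 and 3065.

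The array titled without a genotype (LPS, 45 min) gave 22.5 for Selp, 4483.1 for Gdpd3 and 730.2 for Ifi202b. It correlated best with IL-6-/- plus LPS and IL-6 at 45 min (0.967), and at 0.959 with IL-6-/- and IL-10-/- plus LPS at 45 min. In the latter, Gdpd3 gave 4004 and 163.2 and Ifi202b 690.4 and 43.4, which argues against IL-10-/-. The array titled IL-6-/- whose labels give both times gave 205.1 for Fos, 1295.6 for Selp, 2284.7 for Cav1 and 2108.1 for Gdpd3. It correlated best with IL-6-/- plus LPS and IL-10 at 180 min (0.956), with 0.95 and 0.947 for LPS alone at 180 min in wild type and IL-6-/-. Its Selp and Cav1 lay nearer IL-6-/- with LPS alone (1553 and 2109) than with IL-10 (12450 and 301.8).

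Xist, transcribed from the inactive X chromosome, gave 2241.4 in resting replicate 4 and at most 114.6 in every other grouped array.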
